A study of Homo sapiens with 16 samples.

How the data were processed

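Gene expression was measured in 16 established gastric and gastro-oesophageal cancer cell lines with 2-colour oligonucleotide arrays (Agilent Whole Human Genome), 1 array per line. Per the labels, cultures were harvested below full confluency, total RNA was extracted with a Qiagen RNeasy kit and labelled with an Agilent Quick-Amp kit. Cy3 held a reference of mixed gastric cancer lines on every array and Cy5 the line, with no dye swap. Which lines the reference held, and in what shares, is not given in the sources used here. All lines form 1 group, since the labels name no condition, and each array was treated as a separate sample of it. P-values therefore rest on the spread between these arrays, which holds differences between arrays and slides as well as between lines. Whether a line would repeat cannot be seen.

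Per the file headers, the scanner files were written by Agilent Feature Extraction. Version 9.5.1.1 was used for 11 arrays on 5 slides. Version 10.7.3.1 was used for 5 arrays on 2 other slides (MKN74, OE19, SNU-1, SNU-16 and SNU-5). Each file gives spot intensity in both channels, with the mean, median and background of the spot, flags and a log10 ratio. In the files the deposited intensity column named as background-subtracted equals the mean spot intensity for the 11 arrays, so no subtraction had been made there. The 5 others were taken from the same column. It lay on average 1.00 to 1.01 times the median spot signal. The authors' series table holds the deposited log10 ratio of Cy5 over Cy3. Set against each array's scanner log10 ratio it gave r = 1 on every array, with slopes of 0.99994 to 0.99999, column medians of 0.00679 to 0.02537 and 47 to 502 missing probes, so its scale, centring and direction are those of the scanner's ratio. Per the file headers, Feature Extraction had normalised the dyes by a linear and a LOWESS step for that ratio.

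From the intensities, background was corrected with normexp (offset 50, limma) on the mean signal and the median local background of the spot. Log2 ratios were normalised by loess within each array, with control spots at weight 0. Control spots and spots with an outlier flag (185 to 702 per array) were left out, saturated spots (0 to 5) kept. Spots of a probe were averaged, and the probe with the highest mean intensity stood for a gene. Probe names are those of the array's design and were updated through the RefSeq gene table of assembly GRCh38.p14, used for names, gene order and chromosome only. Of 41000 probes 23434 matched by accession, 2996 by a newer version of it, 1561 by symbol and 588 by an older symbol, and 12421 kept the file's name. That gave 18349 genes with a symbol and 11961 further units. Coordinates are those of the files (hg17). A gene needed a value on 10 or more arrays. The planned filter on the scanner's flag for signal well above background was void, because the flag was set on 100% of gene spots and of negative-control spots. Filters on the 95th percentile of the 153 negative-control spots were therefore added as alternatives. The main fits and list tests had no detection filter. Their lists hold members near the negative controls, such as CBLIF and COL1A2, above them in Cy5 on 0 and 1 arrays. Genes on the Y chromosome and XIST were left out of every named result. The values of 1 amplified gene and of a run of neighbouring genes are not reported here.

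The 5 study genes were tested against 0 with a two-sided sign-flip permutation test. All genes were tested with limma 3.58.1 (R 4.3.3), once for the mean log2 ratio and once for the slope on the ADRM1 log2 ratio, with Benjamini-Hochberg adjustment at 0.05. The 20 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares the genes of a list with all other genes, and fry tests the list by itself against 0. A list called lower, higher, rising or falling by camera is so relative to the other genes. Correlations over lines used 100000 permutations and were repeated without the 2 lines farthest from the ADRM1 median and within the larger array series. The smaller series, with 5 arrays, is under the minimum of 6. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The lists covered the study genes, genes near ADRM1, distal and proximal 20q, 20p, the 19S and 20S proteasome, genes often amplified in gastric cancer, and markers of epithelial, mesenchymal, gastric, intestinal, hepatocyte and yolk sac, neuroendocrine, squamous, proliferating, interferon-responsive, hypoxic, fibroblast and leukocyte states. The fits, the lists, the correlations with neighbours and arms, and most alternatives were fixed before the data were examined. The negative-control filters, the median spot signal, the use of flagged spots, the linear averaging of lists, the chromosome scan and the scan of neighbouring genes were chosen after seeing the data.

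Named genes followed a rule fixed in advance. It took the study genes, the 10 highest and 10 lowest means among genes past the threshold with the same sign in 14 or more lines, the 10 rising and 10 falling with ADRM1 (5 each way where none passed), the 2 genes of each line farthest above the median of the other 15, up to 4 members of each list by mean, association or SD, the 10 largest SDs, PSMA7, UCHL5 and the amplified genes. UCHL5, a deubiquitinase bound by ADRM1, had a mean of -0.16 ± 0.26 and r = 0.0778 with ADRM1.

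The fits were tested on simulated data for 30302 genes, with 100 genes changed by 0.5 and 100 by 1. The simulated noise was normal and independent between genes, with each gene's own SD. Correlation between genes, skewed values and the array series were not simulated. For the mean log2 ratio, 46% of genes with a true effect of 0.5 and 81% with 1 were recovered with 5 false calls. For the slope on ADRM1 the shares were 27% and 58% with 7 false calls. Alternatives covered the log ratios of Feature Extraction, the series table, median centring, no background correction, scale normalisation, all probes of a gene, the Cy5 channel alone, the slide and the array series as terms, an intensity trend, other filters, linear means and each array left out in turn. No column of per-sample values was left unused (0).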

Results

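The series asked how strongly ADRM1 and 4 genes close to it on the long arm of chromosome 20, HRH3, MTG2, LAMA5 and OSBPL2, are expressed in gastric cancer cell lines. ADRM1 is a ubiquitin receptor of the 19S proteasome. HRH3 is a histamine receptor, MTG2 a GTPase of the mitochondrial ribosome, LAMA5 a laminin chain of basement membranes and OSBPL2 an oxysterol-binding protein. Total RNA of 16 established lines was hybridised, 1 array per line, against 1 RNA pool of mixed gastric cancer lines on 2-colour Agilent whole-genome arrays. The lines were AGS, FU97, IM95, KATO III, MKN1, MKN45, MKN7, MKN74, NCI N87, NUGC3, NUGC4, OE19, OE33, SNU-1, SNU-16 and SNU-5. All formed 1 group, and no line had a replicate. Every error below is thus the spread between arrays, 1 per line. It holds differences between arrays, slides and software versions as well as between lines, also where it is called the spread between lines. Ratios are the line (Cy5) over the pool (Cy3) on the log2 scale. The pool's composition is not given in the sources used here. Median spot intensities were 223 to 295 for the pool and 235 to 503 for the lines. Between 73.2% and 85.2% of gene spots in Cy5, and 81.0% to 87.5% in Cy3, exceeded the negative-control spots of the same array. The number of arrays limits the precision. Over all probes, the 120 pairs of arrays correlated with r from -0.107 to 0.482 (median 0.259).

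ADRM1 varied between lines, above the pool in as many lines as below it. The mean log2 ratio was 0.23 ± 0.58 (SD, n = 16), with 8 lines above 0 and 8 below. ADRM1 stood highest in AGS (1.11), NUGC3 (1.02), MKN1 (0.93) and FU97 (0.85), and lowest in MKN74 (-0.82). MTG2 had a mean of 0.09 ± 0.56 and was highest in FU97 (1.11). OSBPL2 had a mean of -0.17 ± 0.62 and was highest in AGS (1.16), and both MTG2 (-1.15) and OSBPL2 (-1.01) were lowest in MKN74, as ADRM1 was. LAMA5 spread most of the 5 genes, with a mean of -0.29 ± 0.86, from 1.19 in OE33 to -1.88 in SNU-1. HRH3 hardly varied (0.03 ± 0.19) and lay near the lower end of the intensity range. None of the 5 means passed against 0 in an exact two-sided sign-flip test over all 65536 sign patterns. The raw p was 0.136 for ADRM1, 0.526 for HRH3, 0.546 for MTG2, 0.201 for LAMA5 and 0.284 for OSBPL2, and the Benjamini-Hochberg values over the 5 genes lay between 0.473 and 0.546. With median centring in place of loess, which leaves the dependence of the ratio on intensity in the data, the ADRM1 mean was 0.71 and passed (adjusted p = 0.0124, n = 16, sign-flip permutation test). In the 11 arrays of the larger series alone the ADRM1 mean was 0.45 and the LAMA5 mean 0.05, and neither passed (adjusted p = 0.107 and 0.891). The other series held MKN74, SNU-1, SNU-16 and SNU-5, with LAMA5 at -0.75, -1.88, -1.56 and -1.16, and OE19 (0.17). In the larger series LAMA5 was also low in AGS (-1.30). Each line was in 1 series only, so line and series cannot be told apart in these spreads. The dyes were not swapped, so each mean also holds any dye effect of the probe. The pool was itself made of gastric cancer lines, so these means compare lines with like lines. Whether a gene is expressed more strongly than in non-cancer tissue cannot be seen from them.

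**Figure D1:**
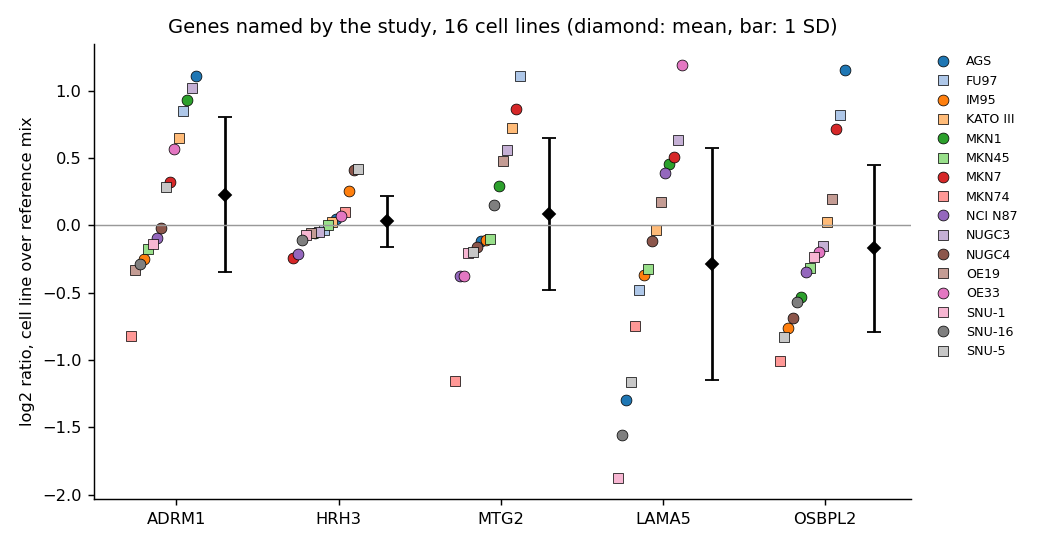
Log2 ratio (cell line over reference mix, y axis) of the 5 study genes, 1 point per cell line, with the mean (diamond) and 1 SD (bar) of the 16 lines. The means lie between -0.29 (LAMA5) and 0.23 (ADRM1), and MKN74 is the lowest line for ADRM1, MTG2 and OSBPL2.

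The probes used lie on chromosome 20 of hg17, the build of the larger array series. ADRM1 (probe A_24_P305597) was measured at 60316517 to 60316576, LAMA5 (A_23_P109269) at 60318697 to 60318756, OSBPL2 (A_24_P408321) at 60304523 to 60304582, HRH3 (A_24_P301837) at 60225122 to 60225181, and MTG2 (A_24_P391229, listed under its older symbol GTPBP5) at 60204368 to 60206329. The files annotate the gene of each probe but not the exon or UTR. For ADRM1 the spread between lines (SD 0.58) was 1.71 times the SD of the same probe's pool signal over the 16 arrays (0.34). The same ratio was 4.16 for MTG2, 5.74 for LAMA5, 2.44 for OSBPL2 and 1.21 for HRH3. Among 18254 named genes, the SD of ADRM1 ranked 7996, that of MTG2 8200, of LAMA5 4189, of OSBPL2 7153 and of HRH3 15482. A second ADRM1 probe followed the first over the lines (r = 0.998), and a second OSBPL2 probe did so with r = 0.887. The other MTG2 probes correlated with the one used at r = 0.485 and r = 0.523 and had means of -0.24, so the MTG2 mean depends on the probe. The second HRH3 probe exceeded the negative controls in Cy5 on 2 arrays and correlated with the first at r = -0.306.

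Among the 877 named genes that were higher than the pool in 14 or more lines, the 10 with the highest means included 3 ribosomal proteins. CNOT1, the scaffold of the CCR4-NOT deadenylase, had a mean log2 ratio of 0.93 ± 0.52 (SD, n = 16) and was higher in 15 lines. ATP2A2, the calcium pump of the endoplasmic reticulum, was higher in all 16 (0.83 ± 0.32). The ribosomal proteins RPS2 (0.80 ± 0.45), RPL3 (0.76 ± 0.45) and RPL4 (0.73 ± 0.45) were higher in 15 of 15, 14 of 15 and 14 of 14 lines with a usable spot. The other named genes were SPRED2, a negative regulator of growth factor signalling (0.73), RAB6C (0.73), RHOT1, a mitochondrial GTPase (0.71), the kinase MAP4K3 (0.69) and GATAD2B, a subunit of the NuRD complex (0.69). In the 11 arrays of the larger series alone, RHOT1 no longer passed (limma, adjusted p = 0.0671). Like those of the study genes, these means also hold any dye effect of the probe.

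The lowest means among genes that were lower than the pool in 14 or more lines, a rule that leaves at most 2 lines above it, belonged to genes that mostly stood high in 1 or 2 lines. AHSG, a plasma protein of liver, had a mean of -4.99 ± 2.30 (SD, n = 16) and was lower than the pool in 15 lines but stood at 3.56 in FU97. AFP, the fetal plasma protein, was likewise lower in 15 lines (-4.46 ± 2.21) and stood at 3.51 in FU97. DMRTB1 (-4.63) stood at 3.42 in IM95, and GNG11 (-4.48) at 0.87 in MKN1. CCN3, a matricellular protein (-4.17), and BCAT1, a branched-chain aminotransferase (-4.20), were highest in MKN1, at 2.88 and 1.99. PRUNE2 (-3.81) was highest in SNU-1 (3.41) and the keratin KRT23 (-3.71) in NCI N87 (2.79) and MKN74 (2.58). SPRR2C (-5.06) and BEX1 (-3.79) were lower in all 15 lines with a usable spot, but the spot left out for its outlier flag was the bright one. With that spot kept, SPRR2C stood at 3.40 in AGS and BEX1 at 1.45 in FU97.

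In all, 3315 genes were higher and 2928 lower than the pool among 30244 tested (limma, Benjamini-Hochberg below 0.05), with 10608 at an unadjusted p under 0.05. Of the 18254 with a matched symbol, 1536 were higher and 2180 lower, 877 and 1073 of them with the same sign in 14 or more lines. Flipping the sign of whole arrays at random gave at most 36 calls in the other patterns of 100 (the real one included). The real signs gave 6348 with missing values filled. Without a dye swap, a dye effect of the probe can keep its sign on every array and is then flipped as well. The contrast therefore cannot tell such an effect from expression. Of the 1826 named genes with the smallest SD, 256 were called higher and 22 lower. Of the next 1825, 512 were called higher and 90 lower. The median means of these sets of genes were only 0.03 and 0.07. The split between directions depended on the scaling, since the log ratios of Feature Extraction gave 5963 higher and 2010 lower genes, and median centring 6083 and 4107. The 11 arrays of the larger series gave 1299 and 1364, and genes above the negative controls in both channels on all arrays 1379 and 2388 of 18106.

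The hepatocyte and yolk sac, mesenchymal, gastric mucosa, intestinal and squamous marker lists lay lower than the other genes by camera with the preset correlation. None of them passed with an estimated one. The lists of this paragraph had median SDs of 1.029 to 1.448. Of the 1826 named genes with the largest SD (median 1.588), 99.07% had means below 0, and of the next 1825 (median 1.075) 92%. Lists were not compared with other genes of like SD, so these calls cannot separate marker identity from spread. The epithelial list, with a median SD of 1.224, did not pass (camera, adjusted p = 0.165). Of the 15 hepatocyte and yolk sac markers, 14 were lower, 14 also when adjusted over the list alone, and none was higher (camera, adjusted p = 7.8e-19; adjusted p = 0.0539 with an estimated correlation). Their median mean log2 ratio was -2.41. Of 18 mesenchymal markers, 10 were lower over all genes, and adjusted over the list alone 12 were lower and 1 higher (p = 1.0e-05; 0.173 with an estimated correlation). VIM, the intermediate filament of mesenchymal cells, had a mean of -2.98 ± 1.81 (SD, n = 16) and was lower in 14 lines, and COL5A1, a fibrillar collagen, -2.20 ± 1.34. Among 19 gastric mucosa markers 8 were lower (p = 0.0021; 0.278 estimated), among them ANXA10 (-2.91 ± 3.44) and CTSE, a gastric protease (-2.89 ± 2.27). Among 17 intestinal markers 7 were lower (p = 0.00154; 0.278 estimated), among them KRT20 (-2.73 ± 1.91) and the trefoil peptide TFF3 (-2.29 ± 2.48). Adjusted over the list alone these were 8 lower and 1 higher gastric and 7 lower intestinal genes. Among 12 squamous markers 5 were lower, 7 adjusted over the list alone (p = 0.000447; 0.24 estimated), TP63 with the lowest mean (-2.33 ± 1.58). Of 20 antigen presentation and interferon genes 7 were lower, 8 adjusted over the list alone (p = 0.000447; 0.278 estimated), led by HLA-DRA (-1.47 ± 1.03). Of 18 genes often amplified in gastric cancer 7 were lower, 12 adjusted over the list alone (p = 9.2e-05; 0.0539 estimated).

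Lists of housekeeping and chromosome 20 genes moved little. The 20S proteasome list had 2 of 14 lower members, 2 also adjusted over the list alone, PSMA3 (-0.45 ± 0.41) and PSMA4 (-0.39 ± 0.37), both of them alpha subunits (camera, adjusted p = 0.0021; adjusted p = 0.278 with an estimated correlation). The distal 20q13.33 list (6 of 38 lower) and the proximal 20q list (11 of 56 lower, 1 higher), with the same counts adjusted over the list alone, passed with p = 0.0222 and 0.008, and with 0.555 and 0.591 with an estimated correlation. All 10 lists that passed by camera lay lower than the other genes, and none of the 20 passed with an estimated correlation. By fry, which tests a list against 0 and not against the other genes, 11 lists passed, but not the same ones. The hypoxia (adjusted p = 0.0215), fibroblast (0.007) and leukocyte (0.00327) lists passed by fry, and the distal (0.117) and proximal 20q lists (0.13) did not. Median centring turned the direction of both 20q lists (adjusted p = 0.276 distal, 0.0182 proximal) and of the 20S list (0.00207). It also turned the 20p and 19S lists above the other genes, both past the threshold. Without IM95 neither 20q list passed (0.0706 and 0.0578), nor the distal list without MKN74 (0.1). The remaining lists did not pass by camera with the preset correlation. They were the study genes (adjusted p = 0.943), the near 20q13.33 genes (0.791), 20p (0.18), the 19S proteasome (0.0852), epithelial (0.165), neuroendocrine (0.881), proliferation (0.0855), hypoxia (0.203), fibroblast (0.098) and leukocyte genes (0.169). The 19S list passed without AGS (0.02), KATO III (0.0404), MKN74 (0.0475) or SNU-5 (0.0166), and the proliferation list without KATO III (0.0214), MKN1 (0.0328), MKN74 (0.049) or NCI N87 (0.0407), both lower than the other genes. A mean of linear ratios cannot lie below that of log ratios, so it moved all list medians upward by arithmetic, to -1.06 for the hepatocyte and yolk sac markers, -0.16 for the mesenchymal, -0.01 for the gastric and 0.04 for the intestinal markers, and to 0.09 for the near 20q13.33 genes and 0.10 for the neuroendocrine markers, which had been above 0.

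**Figure D2:**
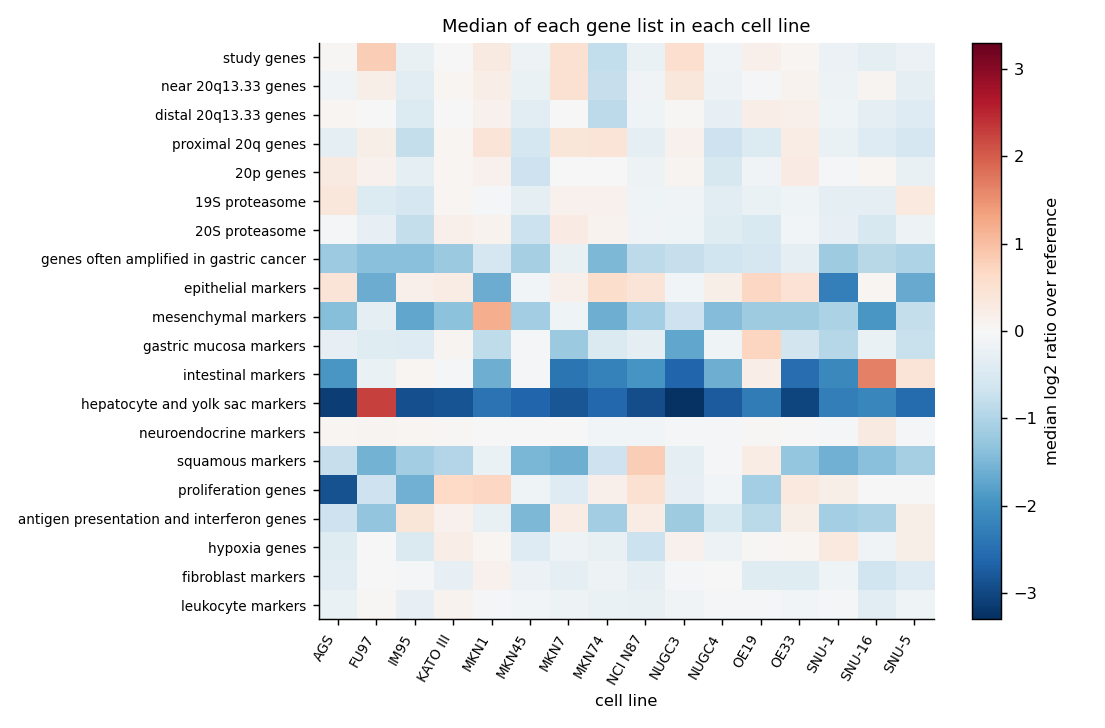
Median log2 ratio over the reference mix (colour) of each gene list (rows) in each cell line (columns). The hepatocyte and yolk sac markers stand at 2.25 in FU97 and at -2.15 or below in the other lines, and the proliferation genes are lowest in AGS at -2.89.

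Single lines stood apart in whole marker programmes. In FU97 the hepatocyte and yolk sac markers had a median of 2.25 over the 12 with a usable spot, and 10 of these were highest there, among them AHSG, AFP and APOH (3.23), a plasma glycoprotein. The spots of TF, APOA2 and SERPINA1 in FU97 carried an outlier flag, and with those spots kept TF and APOA2 stood at 2.16 and 2.15. The albumin gene ALB was highest in SNU-16 (4.80), followed by FU97 (3.66). Intestinal markers were highest in SNU-16 (median 1.65, 14 of 17 above 0), with the adhesion protein CDH17 at 2.95. They were lowest in NUGC3 (-2.61), where CDH17 stood at -3.59. Gastric mucosa markers were highest in OE19 (0.71), with ANXA10 at 3.65 and CTSE at 2.71. Epithelial markers were lowest in SNU-1 (-2.25), where all 18 lay below 0, including the adhesion molecules CDH1 (-4.27) and EPCAM (-5.25). They were also low in SNU-5 (-1.67), FU97 (-1.65) and MKN1 (-1.63). Mesenchymal markers were highest in MKN1 (1.20, 13 of 18 above 0), with VIM at 1.93 and COL5A1 at 2.64. Proliferation genes were lowest in AGS (-2.89), where 19 of the 20 had their lowest value, such as BUB1 (-4.23), CENPF (-4.06) and BIRC5 (-3.96), followed by IM95 (-1.59). These are values of 1 array per line, without a test.

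Several of the genes often amplified in gastric cancer stood high in few lines, while others, such as GATA6 (above 0 in 10 lines) and MDM2 (8 lines), were spread more evenly. ERBB2, a receptor tyrosine kinase, was highest in OE19 (3.12) and NCI N87 (2.07), against a median of -2.87 in the lines other than OE19. Its neighbours on chromosome 17 followed, with GRB7 at 2.15 and 1.19, PGAP3 at 2.06 and 0.97, and MIEN1 at 1.77 and 1.73 in OE19 and NCI N87. STARD3 stood at 1.84 in NCI N87 but at -1.17 in OE19. A second ERBB2 probe was highest in MKN7 (1.47), followed by NCI N87 (1.16). The receptor MET was highest in SNU-5 (2.43), OE33 (2.06) and MKN45 (1.26), and its neighbour CAPZA2 in MKN45 (2.07), SNU-5 (2.03) and OE33 (1.59). Another MET probe was also highest in SNU-5 (2.62), but the remaining one in OE33 (2.38), followed by SNU-5 (2.22). The cyclin CCNE1 stood at 1.76 in MKN7, CCND1 at 1.65 and EGFR at 1.32 in NUGC3, and CD44 at 3.06 in SNU-16. MYC was highest in SNU-16 (1.39) and MKN74 (1.32), GATA4 in FU97 (1.80), GATA6 in NUGC4 (1.84), CDK6 in OE33 (0.50) and MDM2 in MKN74 (1.07). Other probes of MYC, GATA4 and MDM2 differed. They read 0.15 and 0.38 for MYC in SNU-16, GATA4 was highest in AGS (1.42) with 0.76 in FU97, and MDM2 was highest in SNU-16 (1.55), AGS (1.03) or MKN74 (0.78). FGFR2 stood at 0.56 in SNU-16, with the KATO III spot of that probe left out for its outlier flag (2.07 if kept). Its other probes read 4.50 and 2.70 in SNU-16, and 2.81 and 1.89 in KATO III. Expression was measured, not copy number.

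**Figure D3:**
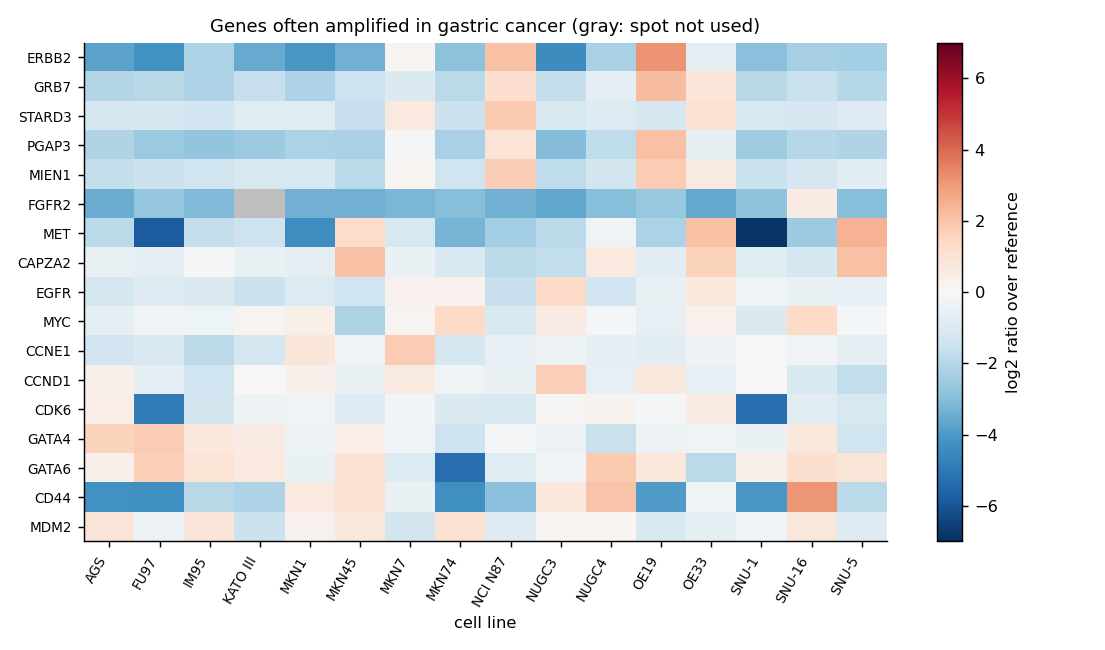
Log2 ratio over the reference mix (colour) of genes often amplified in gastric cancer (rows) in each cell line (columns), 1 probe per gene, with a spot that was not used in gray. ERBB2, GRB7, PGAP3 and MIEN1 are above 0 in OE19 and NCI N87, and MET and CAPZA2 in SNU-5, OE33 and MKN45.

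Over all named genes the largest spread belonged to BNIP3, a mitophagy receptor (SD 4.02, from 3.54 in SNU-1 to -7.48 in NUGC3), TM4SF4 (3.91), IRX2 (3.67), IGFBP1 (3.55), ANXA10 (3.44), PHLDB2 (3.39), RNF128 (3.26), DKK1, an inhibitor of Wnt signalling (3.16), the chemokine receptor ACKR3 (3.14) and ALDH1A3 (3.14). The median SD of named genes was 0.52 between lines and 0.19 for the pool signal. Each line also had genes far above the median of the other 15. The log2 difference was 9.85 for TM4SF4 and 7.84 for ANXA10 in SNU-5, 9.70 for IRX2 and 9.15 for BNIP3 in SNU-1, 9.12 for AHSG and 8.76 for ACKR3 in FU97, and 8.98 for IGFBP1 and 8.51 for TM4SF4 in NUGC4. It was 8.62 for DMRTB1 and 7.76 for DDIT4L in IM95, 8.57 for CCN3 and 8.09 for ACKR3 in MKN1, 8.32 for ANXA10 and 7.34 for CEACAM6 in OE19, and 8.29 for ALB and 6.77 for VAV3 in SNU-16. NCI N87 stood out in KRT23 (7.68) and DAZL (6.97), MKN74 in KRT23 (7.47) and OLR1 (6.06), MKN45 in SPINK5 (7.47) and ANXA10 (7.34), NUGC3 in IL1A (7.26) and MAGEH1 (7.23), and OE33 in EREG (7.23) and MMP1 (6.64). The last were CEMIP (7.14) and SOX2 (6.21) in KATO III, DKK3 (7.09) and THBS1 (7.05) in MKN7, and OLAH (6.45) and IRX2 (6.22) in AGS.

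Whether its neighbours vary with ADRM1 over the lines was asked next. OSBPL2 and MTG2 tended to be high where ADRM1 was high, but neither correlation passed after adjustment over the 4 relations with the processing fixed in advance. For OSBPL2, Pearson's r was 0.576 (permutation p = 0.0198, adjusted 0.0523, n = 16) and Spearman's rho 0.544 (p = 0.0317, adjusted 0.127). For MTG2, r was 0.552 (p = 0.0261, adjusted 0.0523) and rho 0.374 (p = 0.155, adjusted 0.284). LAMA5 had r = 0.286 (p = 0.281, adjusted 0.374) and rho 0.329 (p = 0.213, adjusted 0.284), and HRH3 r = -0.10 (p = 0.714, adjusted 0.714) and rho 0.0294 (p = 0.918, adjusted 0.918). AGS and MKN74 lay farthest from the ADRM1 median. Without them r was 0.327 for OSBPL2, 0.505 for MTG2, 0.459 for LAMA5 and -0.0824 for HRH3. Both pairs passed with median centring (adjusted p = 0.0209 for MTG2 and 0.00504 for OSBPL2), no background correction (0.0478 for both), the mean of all probes (0.0471 and 0.0226) and the median spot signal (0.044 for both), and OSBPL2 also in the Cy5 channel alone (0.00884). Leaving out 1 line brought a pair past the threshold in 8 cases: MTG2 without AGS (r = 0.651), MKN7 (0.577), OE19 (0.631) or OE33 (0.609), and OSBPL2 without MKN1 (0.671), MKN7 (0.606), OE19 (0.646) or OE33 (0.585). The arrays fell into 2 series of different slides and software version. Within the 11 arrays of the larger one, r was 0.57 for OSBPL2, 0.465 for MTG2, -0.0271 for LAMA5 and -0.26 for HRH3. With the series held constant, r was 0.485, 0.466, -0.103 and -0.0582. The other series holds 5 arrays, too few for a correlation.

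ADRM1 correlated with the gene medians of both arms of chromosome 20. Its correlation with the median of the near, distal and proximal 20q genes together was r = 0.606 (two-sided permutation p = 0.0142, adjusted over both arms 0.0284) with rho 0.582 (p = 0.0196, adjusted 0.0196), n = 16 lines. With the median of 37 genes of 20p, taken as the control, it was r = 0.543 (p = 0.029, adjusted 0.029) with rho 0.671 (p = 0.00544, adjusted 0.0109). Without AGS and MKN74 these were 0.691 and 0.607. AGS, highest in ADRM1, had medians of -0.09 for 20q and 0.29 for 20p, and MKN74, lowest in ADRM1, -0.25 and 0.01. In MKN74 the near and distal 20q13.33 lists stood at -0.77 and -0.85, but the proximal 20q list at 0.415. Within the 11 arrays of the larger series r was 0.721 for 20q (p = 0.0156, rho 0.555, p = 0.081) and 0.841 for 20p (p = 0.00088, rho 0.836), and with the series held constant 0.558 (p = 0.0256) and 0.66 (p = 0.00418). For 20q the rank correlation then did not pass (rho 0.421, p = 0.107), and neither did r within the larger series without its 2 farthest lines (0.521, p = 0.148). Without AGS the 20p correlation did not pass (r = 0.469, adjusted p = 0.0783), nor did the 20q correlation in the Cy5 channel alone (r = 0.439, adjusted p = 0.0897). A scan added after the arm medians had been seen gave the median r with ADRM1 for each chromosome. It was 0.194 over 462 genes of chromosome 20, and 0.115 for chromosome 5, the highest of the other 22. On chromosome 20 it was 0.184 for 20p (148 genes) and 0.206 for 20q (314 genes), and the 40 genes within 20 places of ADRM1 in gene order had 0.189. These are correlations of genes, which are not independent replicates.

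**Figure D4:**
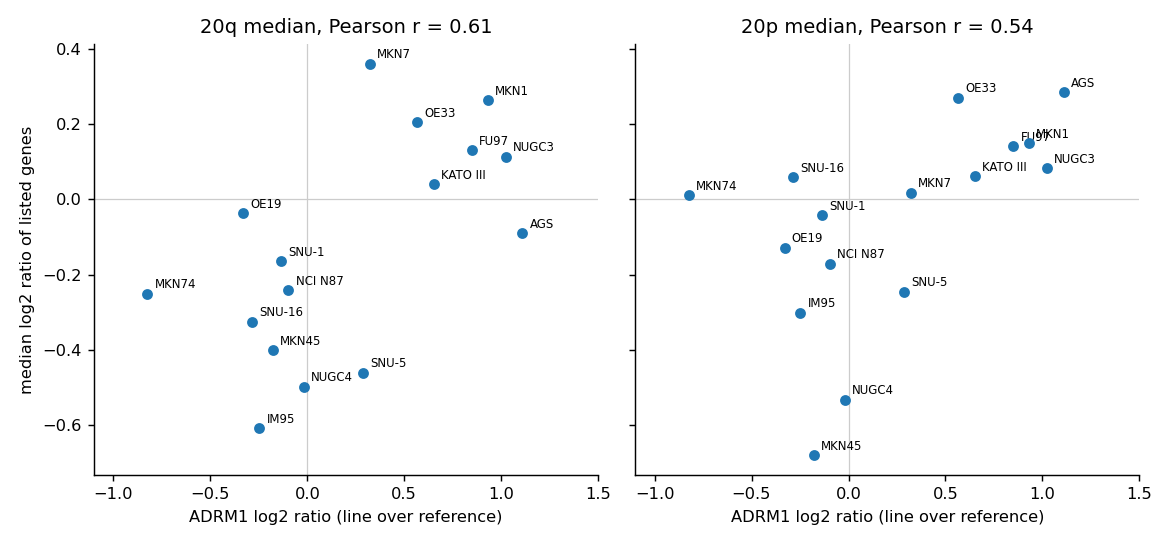
ADRM1 log2 ratio (x axis) against the median log2 ratio of the listed genes of 20q (left) and of 37 genes of 20p (right), 1 point per cell line, all ratios over the reference mix. The Pearson correlation is 0.61 for 20q and 0.54 for 20p.

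**Figure D5:**
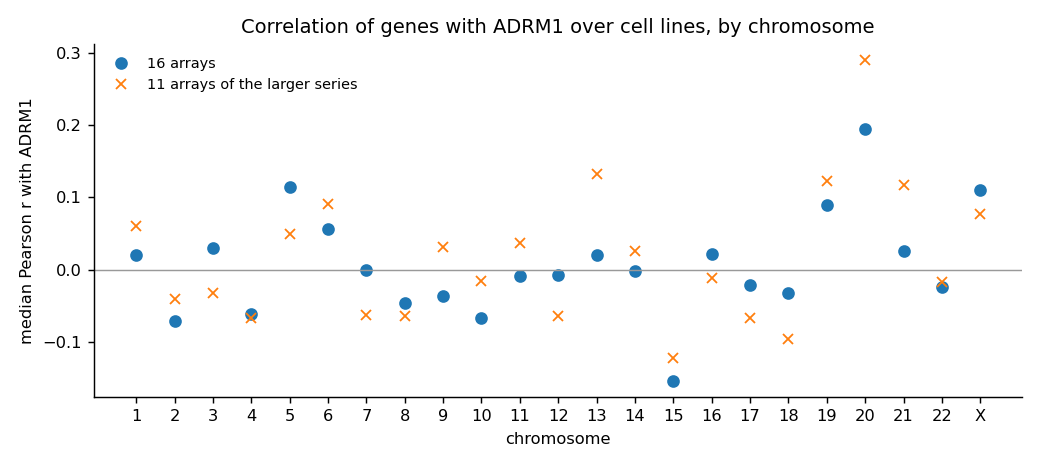
Median Pearson correlation with ADRM1 over cell lines (y axis) of the named genes of each chromosome (x axis), for 16 arrays (circles) and for the 11 arrays of the larger series (crosses). Chromosome 20 is highest in both, at 0.194 and 0.29.

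No single gene was associated with ADRM1 after adjustment, and of the 5 rising genes with the smallest p 4 lie on chromosome 20, but none of the 5 falling ones. The smallest p among rising genes belonged to NSFL1C, a cofactor of the p97 ATPase (slope 0.61 ± 0.10 SE per log2 unit of ADRM1, n = 16, p = 1.9e-05, adjusted p = 0.284), the splicing factor PRPF6 (0.70 ± 0.12), AMN1 (0.81 ± 0.15), the uridine kinase UCKL1 (0.71 ± 0.14) and TPD52L2 (0.79 ± 0.15). AMN1 is the one that lies elsewhere. Among falling genes it belonged to ATP6V1E2 (-0.96 ± 0.17), CCDC121 (-1.07 ± 0.20), GTF3C2 (-0.52 ± 0.11), CCDC17 (-0.57 ± 0.12) and PUS1 (-0.73 ± 0.15). By limma, 0 of 30243 genes passed and 2486 had an unadjusted p under 0.05, and over 100 assignments of the ADRM1 values to arrays (the real one included) the highest other gave 13 calls. Median centring gave 39 rising genes, NSFL1C, PRPF6 and TPD52L2 among them, the Cy5 channel alone 7 rising and 3 falling, and leaving out MKN74 1 each way, with NSFL1C the rising one (adjusted p = 0.00413).

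As groups, the genes of chromosome 20 rose with ADRM1 more than the other genes did, by camera with the preset correlation. Of the 13 near 20q13.33 genes, 10 had a positive slope and 6 rose adjusted over the list alone (camera, adjusted p = 3.6e-05; adjusted p = 0.064 with an estimated correlation). PSMA7, an alpha subunit of the 20S proteasome, had the closest relation (r = 0.797, slope 0.72, unadjusted p = 0.000139), followed by CABLES2 (r = 0.741). Of 38 distal 20q13.33 genes, 31 had a positive slope and 5 rose adjusted over the list alone (p = 5.8e-10; 0.064 estimated). Of 56 proximal 20q genes 45 had a positive slope (p = 7.6e-06; 0.424 estimated), and of 37 genes of 20p 29 did, with 3 rising adjusted over the list alone (p = 5.6e-06; 0.238 estimated), FKBP1A and NSFL1C with the smallest p. Of the study genes, 2 of 4 rose by limma adjusted over the list alone, OSBPL2 and MTG2 (unadjusted p = 0.015 and 0.0211). The permutation test of the same 4 relations did not pass for either (adjusted p = 0.0523 for both), so these 2 calls depend on the test. The proteasome lists, of which ADRM1's complex is a part, also rose. All 14 members of the 20S list and 16 of 19 of the 19S list had a positive slope (p = 0.00313 and 0.00338; both 0.424 estimated), with 1 member of the 20S list, PSMA7, rising adjusted over the list alone. The 19S list did not pass without AGS (adjusted p = 0.117). The mesenchymal list rose, with 15 of 18 slopes above 0 (p = 0.00338; 0.424 estimated), SNAI2 the steepest of its named members (slope 1.97). The antigen presentation list rose too (14 of 20, p = 0.00775; 0.424 estimated), with HLA-C (1.09) rising adjusted over the list alone. Epithelial markers (12 of 18 slopes below 0, p = 0.0364; 0.708 estimated) and proliferation genes (18 of 20, p = 0.0112; 0.717 estimated) fell. In all 10 of 19 lists passed, and 0 with an estimated correlation. Several of these calls hung on 1 line. Without AGS the proliferation list pointed upward (adjusted p = 0.182), and without MKN74 it did not pass (0.117). The mesenchymal list did not pass without MKN1 (0.104), nor the antigen presentation list without MKN74 (0.0868). The epithelial list did not pass without FU97 (0.279), IM95 (0.0753), MKN1 (0.13), MKN74 (0.302), NCI N87 (0.0643), NUGC4 (0.0536) or OE19 (0.118). The antigen presentation list pointed downward in the 11 arrays of the larger series (0.658), and the proliferation list upward with scale normalisation (0.46). No member of the lists for which no count is given passed adjusted over the list alone. The intestinal (0.0748), gastric (0.372), leukocyte (0.322), hepatocyte and yolk sac (0.628), hypoxia (0.749), amplified (0.951), squamous (0.952), neuroendocrine (0.963) and fibroblast (0.963) lists did not pass. Without FU97 the hepatocyte and yolk sac list fell (0.000408). The intestinal list fell without FU97 (0.0486), KATO III (0.0364), MKN74 (0.00387), NCI N87 (0.0451), SNU-1 (0.0497) or SNU-5 (0.0429).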

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

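Each result was computed again under the alternatives named with the methods. Of 883 alternative values of the main results 824 kept their call, 13 lost it, 18 gained it, 28 moved by more than 1.5 times and 0 turned. Of 12014 values of single genes, lists and lines, 11617 kept their call, 242 lost it, 26 moved, 22 turned and the rest gained it. A further 370 values changed sign with neither side past the threshold and are counted as kept, 9 of them main results, such as OSBPL2 at 0.29 and LAMA5 at 0.09 with median centring. The filters on the scanner's detection flag were void and tested nothing, and their values are counted as kept. The series table repeated the Feature Extraction ratio but was counted separately. Counts and SDs could not turn under the rule used. No slope of a named gene on ADRM1 had passed, so these slopes had no call to lose, and 5110 of their values are counted as kept. Each list against the reference is counted with the single genes, lists and lines. The cause was not tested for any of the changes below.

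With median centring the ADRM1 mean was 0.71 (adjusted p = 0.0124, permutation test), 6083 genes were higher, 39 rose with ADRM1, and r was 0.618 for MTG2 and 0.722 for OSBPL2. Lists falling with ADRM1 numbered 0, and against the reference 4 lists passed as higher and 6 as lower than the other genes. Turned upward were the lists distal 20q (adjusted p = 0.276), proximal 20q (0.0182), 20p (0.00094), 19S (5.1e-05) and 20S (0.00207), and the means of DPM1 (0.0455), SEM1 (0.16), PSMD7 (0.14), PSMD2 (0.41), PSMC1 (0.48), PSMA3 (0.12), PSMA4 (0.16), PSMA6 (0.42), PSMB1 (0.55) and HLA-C (0.68). UCHL5 in MKN45 turned to -0.57. The Feature Extraction log ratio and the series value table each gave 5963 higher and 2010 lower genes. The filter above negative controls in both channels on 16 arrays gave 1379 higher genes, and the larger array series 1299 higher and 1364 lower. In that series the antigen presentation list turned against ADRM1 (0.658).

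The correlations of MTG2 and OSBPL2 with ADRM1 given in this paragraph passed. Without background correction r was 0.571 for MTG2 and 0.562 for OSBPL2, with the median spot signal 0.565 and 0.572. The mean of all probes gave 0.567 and 0.661, an HRH3 SD of 0.0934, and 1 list falling with ADRM1. The Cy5 channel alone gave r = 0.702 for OSBPL2 and 0.439 for the 20q median, 7 rising and 3 falling genes and 0 falling lists. With scale normalisation the proliferation list turned against ADRM1 (0.46). The mean of linear ratios turned the medians of the distal 20q list (0.0192) and of the intestinal markers (0.0446), and changed the sign of those of 20p (0.0397), epithelial (0.149), proliferation (0.0451), hypoxia (0.15) and leukocyte genes (0.0106), whose lists had not passed.

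With an estimated correlation in camera, 0 lists rose and 0 fell with ADRM1 and 0 passed against the reference. The adjusted p against ADRM1 was 0.064 for the near and the distal 20q13.33 genes, 0.424 for proximal 20q, 19S and 20S and 0.238 for 20p. By fry 2 lists rose and 0 fell, with 0.276 for proximal 20q and 19S, 0.102 for 20p and 0.252 for 20S.

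With 1 line left out at a time, the genes rising with ADRM1 numbered 0 to 1 and those falling 0 to 1, r was 0.377 to 0.651 for MTG2, 0.458 to 0.671 for OSBPL2 and 0.469 to 0.665 for the 20p median, and 1 to 3 lists fell with ADRM1. The adjusted p was 1.0e-05 to 0.117 for the 19S list, 4.7e-05 to 0.182 for the proliferation list, which turned without AGS, and 0.000408 to 0.827 for the hepatocyte and yolk sac list, which turned without FU97.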

Other observations

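Runs of neighbouring genes stood high together in 1 or 2 lines. The highest runs held members of gene families, such as the metallothioneins MT1A to MT1X in NUGC3 (4.31), which bind metals, the glutathione transferases GSTA1, GSTA2, GSTA3 and GSTA5 in NUGC4 (4.55), the serpins of chromosome 18 in NUGC3 (4.14) and MKN7 (3.22), the pregnancy-specific glycoproteins in MKN7 (3.62), the kallikreins in KATO III (3.41) and NCI N87 (3.06), and the KLRC receptors in SNU-5 (3.38). The highest was a run of the X chromosome in MKN7 with SPANXB1, SPANXA1, SPANXD and MAGEC1 (4.92), and a run on chromosome 4 from LRAT to PDGFC stood high in NCI N87 (3.36). Lower down, at ranks 14 and 17, stood the genes around the receptor ERBB2 in OE19 (median 3.04) and NCI N87 (2.999), and 134 and 154 of 1000 shuffled gene orders held a run as high. In OE19 ERBB2 (5.99), PGAP3 (4.27), GRB7 (3.81) and MIEN1 (3.04) were high, and STARD3 (-0.06), TCAP (0.32) and PNMT (-0.14) were not. These rest on 1 array per line.

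The genes that vary most between lines had means below the pool, and both tests of this were chosen only after the result was seen. Of the 1826 named genes with the largest SD, 1809 had a mean log2 ratio below 0, with a median of -1.02. The median log2 of the mean linear ratio of the same genes was -0.1144. A rise is fixed by the arithmetic and its size by the SD, but not that it ends near 0, so averaging log ratios against a pooled RNA may account for part of the shift. Of these 1809 genes, 96.24% had a line more than 1 log2 unit above 0, but genes picked for a large SD reach that with or without a dye bias of the same size on every array, so such a bias stays open. No biological explanation was tested.

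The genes of chromosome 20 tended to vary with ADRM1. Of the tests below, the comparison between chromosomes, chosen once the correlations with the arm medians were known, and that by distance were chosen only after the result was seen. The median r was 0.1944 on chromosome 20 and 0.1149 on the highest other chromosome, with an SD of 0.0624 among the other 22. Chromosome 20 thus stood above every other chromosome. The arm medians were already known to follow ADRM1, and no other gene was compared with its own chromosome in this way. The comparison therefore cannot exclude a component shared by all chromosomes. Within the 11 arrays of the larger series the median r of 106 named 20q genes was 0.4696, against 0.3236 over 16 arrays, so the difference between the 2 array series does not account for the correlation of these 20q genes. The mean r of ADRM1 with its 20 nearest genes was 0.2709, above that of 89.24% of other genes with their own neighbours. The median r was 0.189 for genes within 20 places of ADRM1 and 0.184 for those more than 200 places away, and 0.13 and 0.275 within the larger series, so co-expression of close neighbours leaves the distant genes open, and no biological explanation was tested.

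For the runs of neighbouring genes, the test of the 10 runs together was chosen only after the result was seen. The run of rank 10 had a median difference of 3.217 and the highest run in 1000 shuffled gene orders 4.36, so a single run of that height may arise from chance alignment of line-specific genes. Of the shuffled orders 0 percent held 10 such runs, and the largest number in any was 2, so chance alignment of 10 runs together was not seen. Of the 10 highest runs 7 were made mostly of genes sharing the first 3 letters of their symbols, so neighbouring probes of one gene family that cross-hybridise may account for those, as may shared control of the family. No biological explanation was tested.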
